A study of Mus musculus with 12 samples.

How the data were processed

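Total RNA had been extracted with a column kit and sequenced as paired-end Illumina libraries, per the labels, from 12 mouse samples labelled Ly6C or Ly6G, spleen or tumor, and numbered 1 to 3. The submitters' processing notes name HISAT2 2.0.5, featureCounts 1.5.0-p3 and the genome build GRCm38. The tool that computed the expression values, its annotation release and any filter are not given in the sources used here. The deposited matrix holds FPKM (fragments per kilobase of gene, relative to all mapped fragments of the library), computed by the authors for each gene and library, with no stated scaling between libraries.

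The matrix held 54674 entries, of which 54104 carried an Ensembl gene identifier and 570 an identifier of an assembled locus that names no gene. The latter took 0.463% to 1.04% of the FPKM of a library (median 0.602%) and were left out of the comparisons. Gene symbols and GRCm38 coordinates came from GENCODE M21, which lacked 66 of the identifiers, and 127 identifiers shared a symbol with another. Fragment counts were not available. Low values times gene length repeated at a step that would correspond to 16.6M to 21.1M fragments per library if a step were 1 fragment, but only 32.4% to 35.4% of low values lay at a multiple of 0.5 steps, so counts were not recovered and no interval for counting error was computed. On that reading, 1 fragment on a gene of 2 kb is 0.0237 to 0.0301 FPKM. A gene with that value or none cannot be told from absent at this depth.

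Genes with at least 1 FPKM in at least 3 of the 12 libraries were tested, which kept 13610. Values were transformed as log2(FPKM + 1). A single model of 4 group means was fitted in limma 3.58.1 (lmFit, contrasts.fit and eBayes with a trend of the variance on the mean, 8 residual and 3.4 prior degrees of freedom), so that all 12 libraries shared an estimate of the spread. It gave tumor against spleen for each label, Ly6C against Ly6G in each tissue, and the difference of the tissue effects between the labels (interaction). Tests were two-sided, and a gene passed at a Benjamini-Hochberg adjusted p under 0.05. The agreement of the tissue effects was described by Pearson's r and Spearman's rho across genes, without p. Replicate numbers were not used as blocks, because nothing in the labels ties a number to an animal.

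Gene lists covered 18 functional groups and 18 cell types or technical signatures. The lists, model, filter, comparisons and rule for naming genes were fixed before the data were examined. Each list was given as members passing over all genes tested and adjusted over the list alone, and lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, which asks only whether a list's genes move on balance one way. Fry passed for 30, 24, 13, 10 and 6 of the 31 tested lists in Ly6C between tissues, Ly6G between tissues, spleen, tumor and the interaction. The counts of a list include each identifier that carries a listed symbol.

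Named genes were the 4 with the highest and the 4 with the lowest change in each comparison among passing genes whose 3 libraries of one group lay beyond those of the other (chance gives 10% of genes), excluding predicted genes and antigen receptor segments; the passing member of each functional list with the largest rise and fall; a fixed set that included Ly6g, Ly6c2, Arg1, Nos2, Cd274, Mapk3 and Mapk14 in every comparison; and the 5 highest and 5 lowest differences of the interaction. Cell type markers were given with up to 3 members of highest mean. Other examples of list members (Myc, Dusp4, Elane, Cxcr2, Csf3r and Ptprc) were picked after their values were seen. A pan-leukocyte list of 20 genes and an adherent cell list of 26 genes were written after the first fit.

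Alternatives were a pseudocount of 0.1 or 5, no expression filter or one at 5 FPKM, rescaling every library to an equal sum (TPM scale), median-of-ratios factors, quantile normalization, fits of 2 groups at a time, the replicate number as a block, no variance trend, array weights, and leaving out each library in turn. Added after the data were seen were rescaling to the geometric mean of the pan-leukocyte genes, removal of S100a8 and S100a9, and leaving out both libraries with the highest mitochondrial share. After removal of S100a8 and S100a9 every library was also rescaled to an equal sum, so those values compare with the TPM scale. The model was tested on simulated data of 13610 genes with the same design. Of genes with a log2 change of 1, 74% to 78% were recovered, and of those with a change of 2, 96% to 99%. Of the calls, 3.33% to 5.95% were false. The simulation drew noise independently for each gene, changed 200 genes and added no shift in scaling or cell composition. These rates need not hold for the real comparisons, where most genes passed between tissues. R 4.3.3, version 1.17.8 of data.table, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used.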

Results

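The data were gene expression values from bulk RNA sequencing of 12 mouse libraries. The labels placed them in 4 groups of 3 libraries, called Ly6C spleen, Ly6C tumor, Ly6G spleen and Ly6G tumor. The series describes them as polymorphonuclear and monocytic myeloid-derived suppressor cells (PMN-MDSCs and M-MDSCs), which are immature myeloid cells that expand in tumor-bearing animals. Ly6G and Ly6C are surface proteins by which these populations are usually told apart. The labels gave neither the sorting gate nor the tumor model, and no library was labelled as treated. Levels are mean FPKM ± SD of 3 libraries. Changes are log2 of FPKM + 1 with the standard error of the limma model (n = 3 per group).

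Total FPKM per library lay between 331680 and 449310, and 10379 to 12337 genes per library reached 1 FPKM. The neutrophil calcium-binding proteins S100a8 and S100a9 took 18.2% ± 4.17 of all FPKM in Ly6C spleen and 27.9% ± 4.0 in Ly6G spleen (SD, n = 3). Their share was 0.484% ± 0.138 in Ly6C tumor and 1.67% ± 0.549 in Ly6G tumor. Mitochondrially encoded transcripts took 2.04% ± 0.421, 2.68% ± 0.199, 5.13% ± 2.45 and 7.63% ± 3.70 in Ly6C spleen, Ly6G spleen, Ly6C tumor and Ly6G tumor, with the highest shares in Ly6C tumor replicate 3 (7.84%) and Ly6G tumor replicate 3 (11.9%). Pearson's r between libraries across genes was 0.970 to 0.986 within groups, 0.933 to 0.972 between the labels in the same tissue and 0.554 to 0.701 between tissues. The first principal component held 84.9% of the variance and the second 5.46%.

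**Figure D1:**
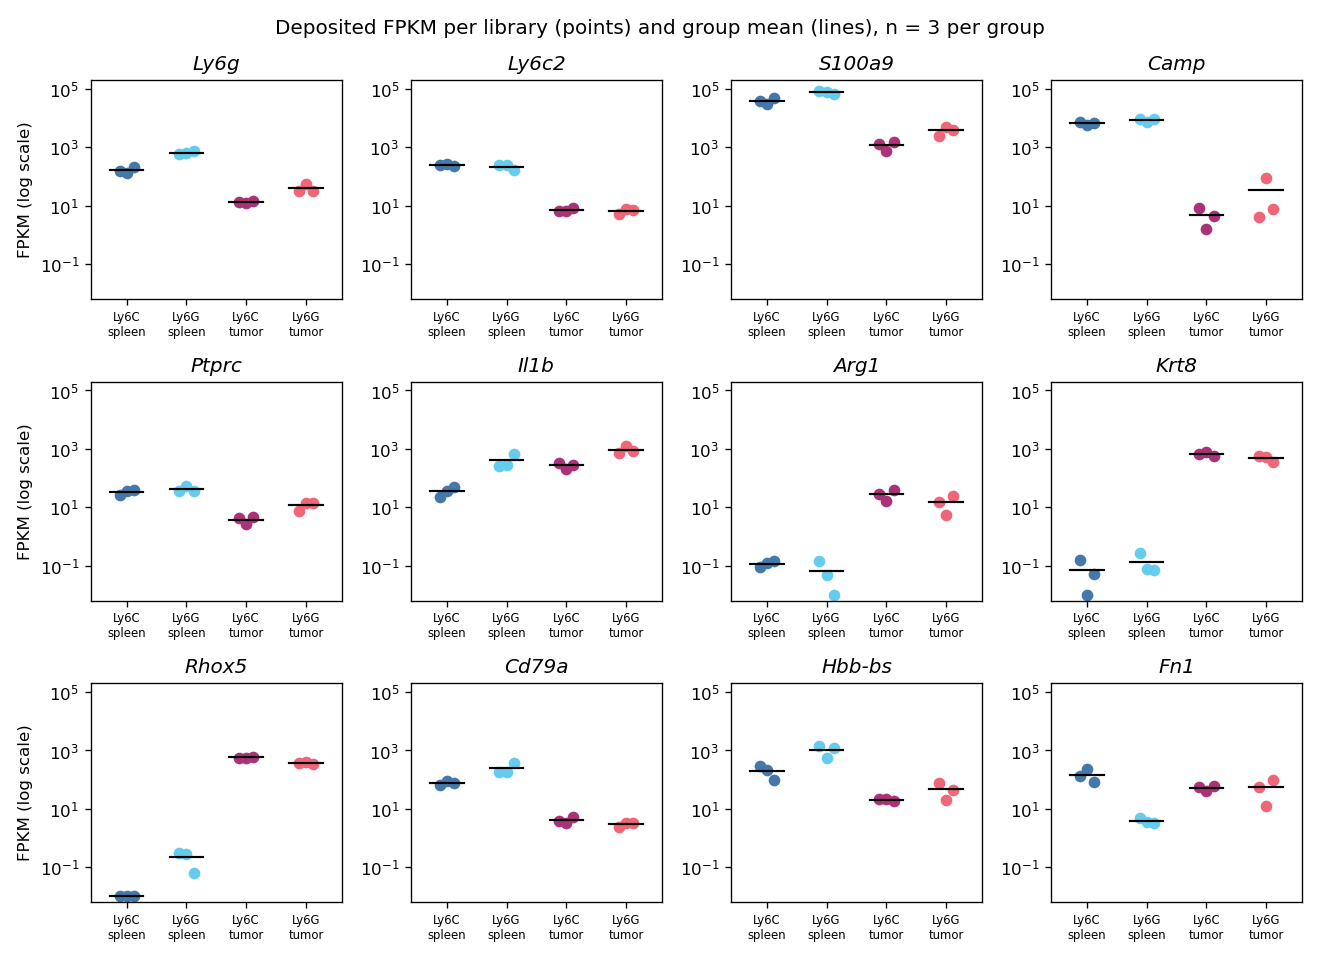
Deposited FPKM of 12 genes (log axis) in the 4 groups, with a point per library, a line at each mean, and values under 0.01 drawn at 0.01. Ly6g lay at 591 to 717 in Ly6G spleen and 131 to 209 in Ly6C spleen, Ly6c2 at 170 to 237 and 223 to 272 in the same groups, and Krt8 at 356 to 770 in the tumor libraries.

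The first question was how Ly6C libraries differed between tumor and spleen. Neutrophil granule genes were the largest falls. Camp, the cathelicidin precursor, fell from 6610 ± 948 to 4.77 ± 3.46 FPKM (log2 change -10.35 ± 0.83), lactoferrin (Ltf) from 5250 ± 1020 to 4.43 ± 2.43, and Ngp from 5550 ± 600 to 6.0 ± 1.59. All 14 secondary and tertiary granule genes fell (median -5.63), as did all 9 primary granule genes (median -4.37), with Fcnb, a ficolin, lowest at -7.51 ± 0.56. The largest rises were the epithelial keratin Krt8, from 0.0694 ± 0.0812 to 670 ± 96.9 (9.29 ± 0.18), the neutrophil-attracting chemokine Cxcl1 (8.16 ± 0.25) and Ltbp3, a matrix protein that binds latent TGF-beta (7.86 ± 0.18). The X-linked homeobox gene Rhox5 was listed at 0 in all 3 spleen libraries and at 576 ± 21.5 in tumor. In the annotation of GRCm38, Camp (ENSMUSG00000038357) spans chromosome 9, 109847379 to 109849617, Krt8 (ENSMUSG00000049382) chromosome 15, 101996698 to 102004482, Cxcl1 (ENSMUSG00000029380) chromosome 5, 90891241 to 90893115, and Rhox5 (ENSMUSG00000095180) chromosome X, 37804842 to 37808876.

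The kinase genes of the MAPK cascade moved both ways in Ly6C libraries, while most genes of the transcriptional response to ERK were higher in tumor. These libraries also gained Krt8 and collagen transcripts and lost Ptprc, so the source cell of a change was not resolved. Of 29 cascade genes, 6 rose and 13 fell. Among p38 isoforms, Mapk12 rose by 3.75 ± 0.13, whereas Mapk13 (-4.01 ± 0.29) and Mapk14 (-1.69 ± 0.22) fell. The ERK gene Mapk3 fell as well (-1.56 ± 0.17). Of 31 response and phosphatase genes, 21 rose and 2 fell. The ETS factor Etv4 rose by 5.18 ± 0.18, the transcription factor Myc by 4.64 ± 0.28 and the phosphatase gene Dusp4 by 4.16 ± 0.21, while the immediate-early gene Ier2 fell by 1.48. Outside the dissociation stress list, with which 5 members are shared, 19 of 26 rose and 0 fell in limma, a split made after the data were seen.

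Genes of secreted factors and of low oxygen were mostly higher in Ly6C tumor, and those of antigen presentation, oxidase and migration mostly lower. Of 25 cytokine and chemokine genes, 19 rose and 2 fell, Tnf among the latter (-1.57 ± 0.14). Of 21 hypoxia genes, 18 rose and 2 fell, led by the vasodilator adrenomedullin (Adm, 5.82 ± 0.23). Of 20 matrix and angiogenesis genes, 14 rose, with osteopontin (Spp1) reaching 997 ± 108 FPKM (7.21 ± 0.18), and 4 fell, with the gelatinase Mmp9 at -4.07 ± 0.37. Alongside these rises, 6 of 9 fibroblast genes, both tested keratins and 18 of 20 adherent cell genes were higher. The immunosuppressive effectors divided into 5 that rose and 8 that fell: arginase Arg1 rose by 4.63 ± 0.41, the nitric oxide synthase Nos2 by 1.37 ± 0.40 and the PD-1 ligand Cd274 by 1.57 ± 0.27, while the inhibitory receptor Pirb fell by 3.54. MHC class II genes included 10 that fell and 0 that rose of 13 (limma; H2-Eb1 -3.08 ± 0.50), and all 10 B cell marker genes fell beside them (median -3.92). NADPH oxidase genes included 6 that fell of 7, Cybb lowest (-5.57 ± 0.21). Of 24 adhesion and chemotactic receptors, 18 fell and 2 rose. The leukotriene receptor Ltb4r1 fell by 4.56 and the chemerin receptor Ccrl2 rose by 2.57 ± 0.18. Beside the oxidase and receptor genes, 19 of 20 pan-leukocyte genes fell in the same libraries (median -3.54). Metabolic and stress lists were mixed: 14 of 25 oxidative phosphorylation genes rose, and so did 13 of 21 glycolysis genes (the lactate transporter Slc16a1 by 3.88 ± 0.19) with 4 falls (Hk3, -4.55 ± 0.26). Rises were also seen in 13 of 21 stress response genes (the chaperone Pdia6 by 3.41 ± 0.16) with 3 falls, and 10 of 18 oxidative stress genes (Srxn1 by 3.85 ± 0.12) with 3 falls. Cell cycle genes showed 17 falls (Plk1, -2.24 ± 0.20) and 4 rises, interferon response genes 9 falls (Cmpk2, -2.19 ± 0.15) and 1 rise, and lipid genes 4 of each.

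Markers of cell types also differed between Ly6C tumor and Ly6C spleen, both of cells other than MDSCs and of neutrophils and monocytes. Of 8 epithelial genes, only Krt8 and Krt18 reached the expression filter, and both rose. The list's median level was 0.146 ± 0.0257 FPKM in Ly6C tumor. Of 9 fibroblast genes, 6 rose, the collagen Col3a1 from 0.0191 ± 0.0128 to 236 ± 81.4. The leukocyte gene Ptprc fell from 33.9 ± 6.63 to 3.76 ± 1.05. B cell genes (10 of 10 fell), T cell genes (7 of 7), erythroid genes (9 of 11), neutrophil genes (12 of 14) and monocyte genes (13 of 14, Ly6c2 -4.95 ± 0.17) were mostly lower, and Ly6g itself fell by 3.55. Macrophage genes (4 rose and 4 fell of 14), red pulp macrophage genes (1 and 4 of 8), endothelial genes (3 and 1 of 5), megakaryocyte genes (2 and 1 of 4) and dissociation stress genes (4 and 3 of 11) went both ways. All 4 tested eosinophil genes and both tested dendritic cell genes fell, 1 of 2 mast cell genes fell, the melanocyte gene Pmel fell, 10 of 13 mitochondrially encoded genes rose, and no NK cell gene reached the expression filter.

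Of 13610 genes tested in limma, 10443 passed between Ly6C tumor and Ly6C spleen, 6289 higher and 4154 lower in tumor, and 3907 and 2358 of these by at least 2-fold. Adjusted over the list alone, the counts of the lists above were the same except for oxidative phosphorylation (12 higher), lipid handling (2 higher), matrix (5 lower), erythroid (10 lower) and mast cell genes (1 higher). The camera set test passed for 19 of 31 lists, among them secondary granules (adjusted p = 9.29e-08), ERK response (0.00391) and MAPK cascade (0.0427, down). Of these, 0 held with an estimated correlation (lowest adjusted p = 0.343 with an estimated correlation, 3 lists with an unadjusted p under 0.05). The MAPK cascade call was lost without Ly6C spleen replicate 3 and without Ly6C tumor replicate 1 (adjusted p = 0.0545 for each). The immunosuppressive and macrophage lists had a positive mean (0.13 and 0.07) but a negative median and a downward set test. The higher share of passing genes was 60.2% as deposited, 57.1% on the TPM scale, 51.1% with median-of-ratios factors and 50% after quantile normalization. It was 49% on the TPM scale without S100a8 and S100a9. With each library rescaled to 20 pan-leukocyte genes, chosen after the data were seen, 12231 genes were higher and 564 lower, and the median change of all genes moved from 0.27 to 2.99. Of 19 lists in which more genes passed as lower than as higher, 10 turned to more higher than lower genes (the cell cycle, interferon, MHC class II, neutrophil and monocyte lists among them). Both granule lists, NADPH oxidase, B cell, T cell, eosinophil and erythroid lists still had more lower genes. The MAPK cascade, immunosuppressive and adhesion receptor lists no longer had more lower than higher genes.

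The second question was how Ly6G libraries differed between tumor and spleen. Granule genes were again the largest falls: Camp from 8430 ± 1180 to 33.6 ± 47.9 FPKM (-9.04 ± 0.83), Ltf (-8.26 ± 0.70) and Ngp (-7.79 ± 0.53). The tumor mean of Camp rested on Ly6G tumor replicate 2 (88.9 FPKM, against 4.17 and 7.77 in replicates 1 and 3). The fourth under the naming rule was Ly6d, a surface protein of the Ly6 family (-6.49 ± 0.28). That rule leaves out antigen receptor segments, and the B cell marker Ighm fell further (-7.44 ± 0.38). In all, 13 of 14 secondary and tertiary granule genes (median -4.71) and 9 of 9 primary granule genes (median -3.41) fell, with the protease inhibitor Serpinb1a at -6.43 ± 0.32. Krt8 (8.71 ± 0.18), Rhox5 (8.27 ± 0.11), Ltbp3 (8.0 ± 0.18) and Cxcl1 (7.88 ± 0.25) had the largest rises. Ly6g fell from 651 ± 63.6 to 39.1 ± 13 and Ly6c2 from 214 ± 38.6 to 6.69 ± 1.27. Ly6g (ENSMUSG00000022582) spans chromosome 15, 75155240 to 75159126, and Ly6c2 (ENSMUSG00000022584) chromosome 15, 75108158 to 75111970.

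In Ly6G libraries, 29 of 31 ERK response and phosphatase genes rose in tumor and 1 fell. In the same libraries Krt8 rose from 0.136 ± 0.109 to 483 ± 113 FPKM, 8 of 9 fibroblast genes rose and 19 of 20 pan-leukocyte genes fell, so the source cell was not resolved. The AP-1 subunit Fosl1 rose from 3.94 ± 1.35 to 284 ± 34.7 FPKM (5.87 ± 0.23), and Ier2 fell by 1.26. The dissociation stress list, which holds Fos, Fosb, Jun, Egr1 and Ier2 as well, was higher alongside it (9 of 11 genes, median 2.69). Of the 26 ERK response genes outside that list, a split made after the data were seen, 26 rose (median 2.22). MAPK cascade genes were 12 higher and 10 lower of 29, a balance that turned to 6 higher and 15 lower with median-of-ratios factors and 8 higher and 14 lower after quantile normalization. Mapk12 rose by 3.26 ± 0.13, and Mapk13 (-3.58 ± 0.29), Mapk3 (-1.51 ± 0.17) and Mapk14 (-1.04 ± 0.22) fell.

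Secreted factors, hypoxia and matrix genes were again mostly higher, with 19 of 25 cytokine genes up and 3 down (the cytokine Osm, -1.24 ± 0.25), 18 of 21 hypoxia genes up and 2 down (Adm 5.34 ± 0.23), and 15 of 20 matrix genes up and 4 down (Spp1 7.09 ± 0.18), alongside the fibroblast and keratin genes and 18 of 20 adherent cell genes. Immunosuppressive effectors showed 5 rises and 7 falls, with the prostaglandin synthase Ptges (4.59 ± 0.36), Arg1 (3.68 ± 0.41), Cd274 (2.64 ± 0.27) and Nos2 (2.22 ± 0.40) higher and the checkpoint protein Vsir (-2.78 ± 0.27) lower. MHC class II genes showed 11 falls (H2-Aa -4.94 ± 0.47) and 1 rise, the costimulatory ligand Cd80 (1.01 ± 0.16). B cells carry MHC class II too, and their 10 marker genes all fell in the same libraries (median -5.52; Cd79a from 247 ± 102 to 3.02 ± 0.568 FPKM). NADPH oxidase genes showed 6 falls of 7. Migration receptors showed 15 falls (the formyl peptide receptor Fpr2 -3.37 ± 0.25) and 3 rises (Ccrl2 4.21 ± 0.18). Beside them, 19 of 20 pan-leukocyte genes fell (median -2.53). Glycolysis genes were 14 higher and 2 lower of 21, stress response genes 16 and 1 of 21, oxidative stress genes 9 and 3 of 18, and interferon genes 4 and 9 of 21. Oxidative phosphorylation genes were 9 higher and 5 lower as deposited but 4 and 13 with median-of-ratios factors, and cell cycle genes 5 and 11 but 11 and 6 on the TPM scale. Lipid genes were 6 higher and 5 lower, but 4 and 8 with those factors and 5 and 8 after quantile normalization.

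Marker lists in Ly6G libraries showed 8 of 9 fibroblast genes and both tested keratins higher, and B cell (10 of 10), T cell (7 of 7), erythroid (10 of 11), eosinophil (4 of 4), dendritic cell (2 of 2), melanocyte (1 of 1), monocyte (10 of 14) and red pulp macrophage genes (5 of 8, with 1 higher) lower in tumor. Neutrophil genes were 10 lower and 1 higher of 14, macrophage genes 6 and 3 of 14, endothelial genes 1 and 4 of 5, mast cell genes 1 and 1 of 2, and dissociation stress genes 1 and 9 of 11. Of 13 mitochondrially encoded genes, 6 rose. Megakaryocyte genes were 3 higher and 1 lower of 4, but 1 and 2 after quantile normalization.

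Between Ly6G tumor and Ly6G spleen, 10367 of 13610 genes passed in limma, 7010 higher and 3357 lower in tumor. Adjusted over the list alone, the list counts were the same except for 20 higher cytokine genes. In camera, 18 of 31 lists passed, among them secondary granules (adjusted p = 1.03e-08) and ERK response (0.000213). Of these, 0 held with an estimated correlation (lowest adjusted p = 0.305 with an estimated correlation, 2 lists with an unadjusted p under 0.05). For immunosuppressive effectors the mean was positive (0.40) and the median negative (-0.50), and for oxidative phosphorylation and lipid genes the median was positive while the set test pointed down, none of them passing. The interferon list passed (adjusted p = 0.0248) but not without Ly6G spleen replicate 3 (0.126). The higher share of passing genes was 67.6% as deposited, 76.0% on the TPM scale, 51.1% with median-of-ratios factors and 49.8% after quantile normalization, and the median change of all genes was 0.43, 0.82, 0.03 and -0.02. Rescaled to pan-leukocyte genes, 11934 genes were higher and 583 lower, the median was 2.11, and of 18 lists with more lower than higher genes 7 turned to more higher ones. The immunosuppressive and adhesion receptor lists no longer had more lower than higher genes.

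**Figure D2:**
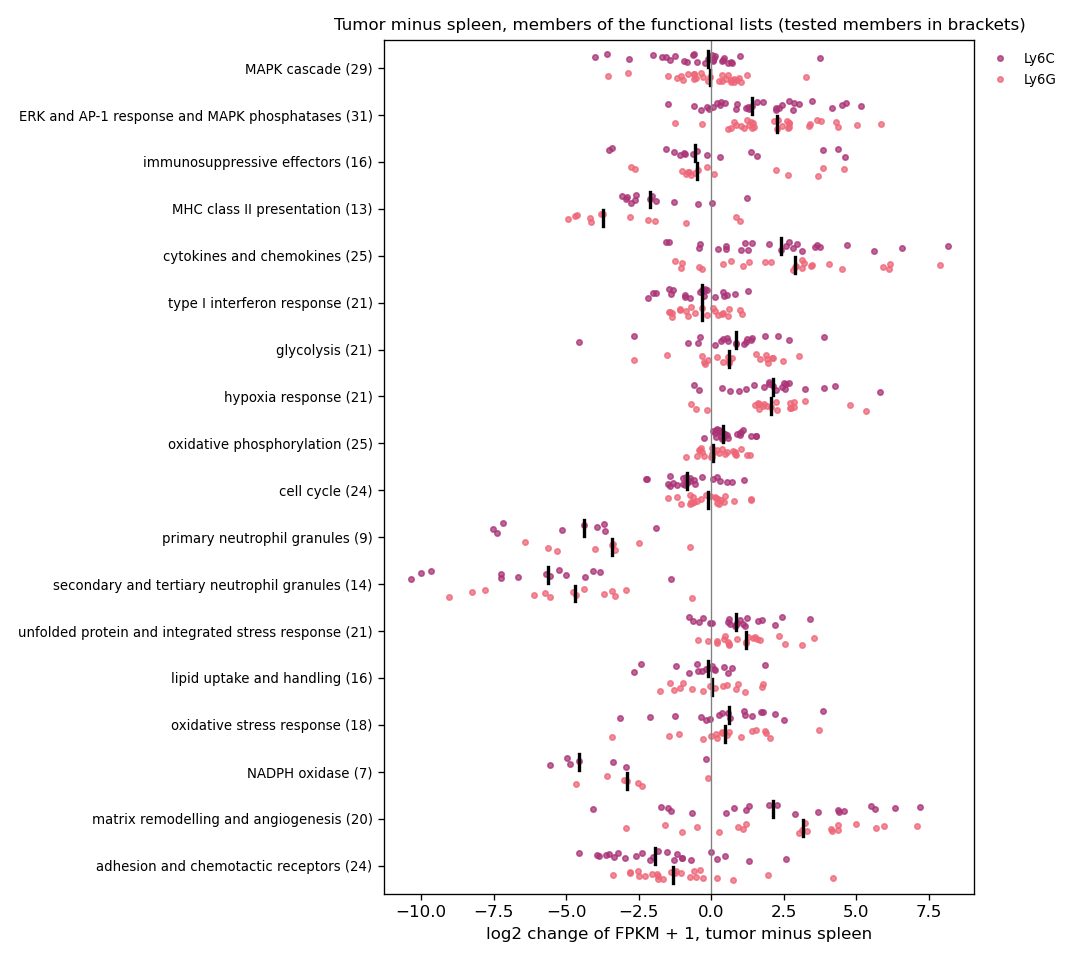
Log2 change of FPKM + 1 from spleen to tumor (x axis) of each tested member of the 18 functional lists (y axis), in Ly6C and in Ly6G (colors), with a bar at each list's median. Secondary granule genes had medians of -5.63 in Ly6C and -4.71 in Ly6G, and ERK response genes medians of 1.40 and 2.28. The Ly6G directions of the MAPK cascade, oxidative phosphorylation, lipid and cell cycle lists changed with the scaling.

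Both labels changed together between the tissues. Across the 13610 genes, the tumor-spleen changes of Ly6C and Ly6G had Pearson's r = 0.917 and Spearman's rho = 0.894, with genes not being independent replicates. Passing genes were higher in both labels in 5668 cases and lower in both in 2923, where independent calls would give 3239 and 1025. Opposite directions were seen for 245 passing genes. In each label, 18 of 20 adherent cell genes were higher in tumor and 19 of 20 pan-leukocyte genes lower. The agreement between the labels therefore cannot be assigned to the sorted cells. Within-tissue differences between the labels were far less correlated, with r = 0.152 and rho = 0.0508 between spleen and tumor. They were also smaller, with 897 passing genes in spleen and 441 in tumor at 2-fold or more. Between tissues, 6265 in Ly6C and 6064 in Ly6G reached that size. Smaller differences can lower a correlation through noise alone, so the correlations are not directly comparable.

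The third question was how the labels differed in spleen. Ly6g was lower in Ly6C spleen than in Ly6G spleen (166 ± 40.0 against 651 ± 63.6 FPKM, -1.99 ± 0.22), while Ly6c2 did not differ (247 ± 24.8 against 214 ± 38.6, 0.22 ± 0.17, adjusted p = 0.380), except that it passed on the TPM scale (0.0207). Fibronectin (Fn1, 146 ± 73.5 against 3.83 ± 0.832, 4.82 ± 0.59) and the clotting factor subunit F13a1 (54.0 ± 29.3 against 2.04 ± 0.110, 4.04 ± 0.36), both made by monocytes, were higher in Ly6C, as was Fam129b (3.35 ± 0.33). The inflammatory cytokine Il1b (35.3 ± 13.5 against 408 ± 239, -3.42 ± 0.39), the metalloreductase Steap4 (-3.35 ± 0.43) and the lectin Clec4d (-2.95 ± 0.33) were lower. Fn1 (ENSMUSG00000026193) spans chromosome 1, 71585520 to 71653200, F13a1 (ENSMUSG00000039109) chromosome 13, 36867178 to 37050244, and Il1b (ENSMUSG00000027398) chromosome 2, 129364570 to 129371139. A pair of the genes with the largest differences carried a limit. Hgs (ENSMUSG00000025793, 3.77 ± 0.50) shares its span on chromosome 11, from 120467635, with another identifier of the same symbol (ENSMUSG00000116045) whose difference was -0.69 ± 0.28. Hist2h2aa1 (-6.46 ± 1.78) belongs to a family of nearly identical histone copies and was listed at 0 in Ly6C spleen.

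All 24 cell cycle genes were higher in Ly6C spleen (median 1.0, with the mitotic activator Cdc20 at 1.67 ± 0.19). They numbered 24 on the TPM scale, 21 with median-of-ratios factors and 20 after quantile normalization. After pan-leukocyte rescaling 8 passed as higher at a median of 1.02, in a fit that shared its spread with the tumor libraries. Of 9 primary granule genes, 5 were higher and 0 lower in limma (the granulocyte factor Cebpe 1.3 ± 0.31; neutrophil elastase Elane 1.20 ± 0.31), and 2 after that rescaling, whereas secondary granule genes gave 1 higher and 1 lower of 14. Of 14 monocyte genes, 6 were higher (Ccr2 1.61 ± 0.45, a call lost without Ly6C spleen replicate 2 or Ly6G spleen replicate 2 or 3, at an adjusted p of up to 0.0707). Neutrophil genes were lower for 10 of 14 (median -1.08; the chemokine receptor Cxcr2 -1.21 ± 0.33), interferon response genes for 9 of 21 (Rsad2 -1.70 ± 0.25) with 3 higher and 7 lower on the TPM scale, and immunosuppressive effectors for 6 of 16 (arginase Arg2 -2.77 ± 0.31), with Tgfb1 alone higher (1.33 ± 0.27). Cytokine genes were 4 higher (Ccl9 2.42 ± 0.43) and 8 lower, and MHC class II genes 4 lower (H2-Aa -1.76 ± 0.47, lost without Ly6G spleen replicate 3, adjusted p = 0.0566), beside 10 of 10 B cell genes (median -1.42), whose cells carry MHC class II too. Adhesion receptors were 1 higher and 6 lower (Fpr1 -1.94 ± 0.30). ERK response genes were 7 higher (Jun 1.59 ± 0.23) and 2 lower (Ier3 -0.87 ± 0.16), and stress response genes 8 higher and 2 lower (Chac1 -0.87 ± 0.18).

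The direction of 4 lists in spleen changed with the scaling. MAPK cascade genes were 6 higher (Mapkapk3 1.22 ± 0.17) and 4 lower (Mapk11 -1.0 ± 0.16) as deposited, 2 and 6 with median-of-ratios factors, and 3 and 5 after quantile normalization. Hypoxia genes were 4 higher and 3 lower but 1 and 7 and then 0 and 4 under those scalings, oxidative phosphorylation genes 4 and 0 (Cyc1 0.87 ± 0.15) but 1 and 4 with median-of-ratios factors, and oxidative stress genes 1 and 2 but 4 and 1 on the TPM scale. Glycolysis genes were 3 higher and 3 lower (Hk2 1.07 ± 0.19) and NADPH oxidase genes 1 and 1, ties from which no turn could be counted. Among lists that did not turn, lipid genes were 4 higher (the scavenger receptor Msr1 1.43 ± 0.35) and 2 lower (Fabp5 -1.14 ± 0.27), and matrix genes 3 and 2. On the TPM scale the median difference of all genes moved from 0.11 to 0.40. Arg1, Nos2, Cd274, Mapk3 and Mapk14 did not pass as deposited. Nos2 (-0.97 ± 0.40, adjusted p = 0.0878) passed without Ly6C spleen replicate 3 and without Ly6G spleen replicate 3 (lowest 0.0281), Cd274 (-0.72 ± 0.27, 0.0670) without Ly6C spleen replicate 2 and without Ly6G spleen replicate 1 (lowest 0.0204), and Mapk14 (0.44 ± 0.22, 0.158) without Ly6G spleen replicate 2 and on the TPM scale (lowest 0.0182).

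Transcripts of other spleen cells were lower in the Ly6C libraries, with 10 of 10 B cell genes (Cd79a 77.1 ± 11.3 against 247 ± 102 FPKM), 7 of 7 T cell genes, 11 of 11 erythroid genes (Hbb-bs 200 ± 97.9 against 1050 ± 434) and 7 of 8 red pulp macrophage genes lower. Of the 36 tested members of these 4 lists, 35 were lower as deposited, 24 on the TPM scale, 35 with median-of-ratios factors, 34 after quantile normalization and 9 after pan-leukocyte rescaling. Macrophage genes gave 1 higher and 1 lower of 14, megakaryocyte genes 1 and 1 of 4, eosinophil genes 1 lower of 4, mast cell genes 1 lower of 2, dissociation stress genes 3 higher of 11, and the dendritic cell, fibroblast, endothelial, epithelial, melanocyte and mitochondrially encoded lists had 0 passing members in limma and 0 adjusted over the list alone.

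In spleen, 4171 genes passed in limma, 3002 higher and 1169 lower in Ly6C, with 579 and 318 by at least 2-fold. Adjusted over the list alone, 9 MAPK cascade genes were higher and 5 lower, 6 ERK response genes higher and 1 lower, 8 immunosuppressive effectors, 9 cytokine genes and 11 neutrophil genes lower, 5 hypoxia and 2 oxidative phosphorylation genes higher, 3 stress response and 2 megakaryocyte genes lower, and 0 macrophage genes lower, with the other counts as above. Camera passed 14 of 31 lists, including cell cycle (adjusted p = 2.14e-11), B cell (6.19e-09) and primary granules (0.0334). The last call was lost without Ly6C spleen replicate 1 (0.0664) or 3 (0.0879) and without Ly6G spleen replicate 3 (0.210). Of the 14, 0 held with an estimated correlation (lowest adjusted p = 0.296 with an estimated correlation, 3 lists with an unadjusted p under 0.05). For the ERK response, lipid and matrix lists the median was positive and the set test pointed down, and glycolysis had a negative median, a positive mean and a downward test, none passing. The higher share of passing genes was 72.0% as deposited, 90.6% on the TPM scale, 42.9% with median-of-ratios factors and 53.0% after quantile normalization. It was 82.6% on the TPM scale without S100a8 and S100a9. Rescaled to pan-leukocyte genes, 262 genes passed, 184 higher and 78 lower. That fit shared its spread with the tumor libraries. Their factors ran from 0.146 to 0.299 in Ly6C and from 0.369 to 0.646 in Ly6G, against 2.615 to 2.824 and 2.912 to 3.184 in spleen. The spread that this adds in tumor can lower the spleen count without any change in the spleen differences.

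The fourth question was how the labels differed in tumor. Ly6g was lower in Ly6C tumor than in Ly6G tumor (13 ± 1.03 against 39.1 ± 13 FPKM, -1.48 ± 0.22) and Ly6c2 did not differ (7.05 ± 0.976 against 6.69 ± 1.27, 0.07 ± 0.17, adjusted p = 0.818). The MYC antagonist Mxd1 (-2.28 ± 0.44), Kctd12 (-2.12 ± 0.26), the chemokine Ccl3 (38.3 ± 9.35 against 143 ± 24.7, -1.89 ± 0.25), Ccrl2 (-1.83 ± 0.18), the glucose transporter Slc2a3 (-1.82 ± 0.29), Cd274 (8.53 ± 1.85 against 31.8 ± 6.67, -1.78 ± 0.27), the oxidase subunit Ncf1 (-1.72 ± 0.27), the cholesterol exporter Abca1 (-1.36 ± 0.24), Cd80 (-1.33 ± 0.16) and the stress kinase Map3k5 (-1.21 ± 0.17) were lower in Ly6C. Kctd12 (ENSMUSG00000098557) spans chromosome 14, 102976581 to 102982637, Ccl3 (ENSMUSG00000000982) chromosome 11, 83647844 to 83649355, and Cd274 (ENSMUSG00000016496) chromosome 19, 29367455 to 29388095. Arg1 (1.02 ± 0.41, adjusted p = 0.112), Mapk3 and Mapk14 did not pass.

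By list, 13 of 14 neutrophil genes were lower in Ly6C tumor (median -1.69; the cytokine receptor Csf3r -2.07 ± 0.30), as were 10 of 14 secondary granule genes, 14 of 24 adhesion and chemotactic receptors (Cxcr2 -1.70 ± 0.33), 10 of 21 interferon genes, 9 of 16 immunosuppressive effectors, 10 of 25 cytokine genes with 1 higher, and 4 of 7 NADPH oxidase genes. Genes shared by most leukocytes were lower as well (16 of 20, median -1.12), and after rescaling to them the lower genes numbered 4 in the neutrophil list, 3 in the cytokine list, 1 each in the secondary granule and immunosuppressive lists, and 0 in the interferon and NADPH oxidase lists. Oxidative phosphorylation genes were higher for 13 of 25 and cell cycle genes for 6 of 24, but on the TPM scale for 3 and 0, where 0 of either list was lower in limma. The MAPK cascade, ERK response, stress response and lipid lists had 4 lower genes each, glycolysis 5, hypoxia 2, MHC class II 1, oxidative stress 1 and matrix 2 with 1 higher, while primary granule genes had 0 passing members as deposited and adjusted over the list alone. Among markers, endothelial genes were lower for 3 of 5, red pulp macrophage and dissociation stress genes for 2, eosinophil, mast cell and megakaryocyte genes for 1 each, and 1 of 14 monocyte genes was higher. The B cell, T cell, erythroid, macrophage, dendritic cell, fibroblast, epithelial, melanocyte and mitochondrially encoded lists had 0 passing members in limma.

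Of 13610 genes, 1974 passed in tumor, 790 higher and 1184 lower in Ly6C, and 6 and 435 of these by at least 2-fold, with 4340 under 0.05 unadjusted. That count fell to 746 without Ly6G tumor replicate 3, 750 without Ly6C tumor replicate 3, 763 without Ly6C tumor replicate 2, 1018 without Ly6G tumor replicate 2 and 1117 without Ly6C tumor replicate 1, was 1324 without Ly6G tumor replicate 1, and was 260 without both libraries of the highest mitochondrial share, a choice made after the data were seen. The balance of directions did not hold either, since the higher genes fell from 790 to 79 without Ly6C tumor replicate 3, 115 without Ly6G tumor replicate 3, 116 without Ly6C tumor replicate 2 and 9 without both libraries of the highest mitochondrial share. Their share was 10.5%, 15.4%, 15.2% and 3.46% in those fits, and 53.5% with a pseudocount of 5. Calls that were lost when a single library was left out included Nos2 (-1.82 ± 0.40; without Ly6C tumor replicate 2 or Ly6G tumor replicate 3, adjusted p up to 0.0621), Mmp9 (-1.70 ± 0.37; the same libraries, up to 0.0606), Ndufs8 (0.65 ± 0.14; without replicate 3 of either group, up to 0.0581) and Leng1 (1.36 ± 0.29; without Ly6C tumor replicate 2 or 3, up to 0.0566). Those of Egr1 (-2.14 ± 0.58), Ifit3, Hmox1, Timp1 and Mgat1 were lost without any 1 of the 6 tumor libraries, and those of Ms4a4c, Tmem254c, Ngp, Hgs, Ccl7, Ero1l, Ppp1r15a and Pcna without any 1 of at least 4 of them.

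Adjusted over the list alone, more members passed in tumor in several lists: 20 oxidative phosphorylation and 16 cell cycle genes higher, 15 interferon genes, 11 immunosuppressive effectors (with 1 higher), 16 migration receptors (with 2 higher), 11 secondary granule, 6 MAPK cascade, 6 glycolysis, 5 ERK response and 4 endothelial genes lower, 2 cytokine and 2 epithelial genes higher, and 0 oxidative stress genes. Camera passed 12 of 31 lists, including neutrophil (adjusted p = 7.9e-12) and oxidative phosphorylation (4.13e-09), and 0 held with an estimated correlation (lowest adjusted p = 0.242 with an estimated correlation, 5 lists with an unadjusted p under 0.05). The ERK response call (0.0124) was lost without Ly6C tumor replicate 3 (0.117) and without Ly6G tumor replicate 1 (0.0855), the MAPK cascade call (0.0305) without Ly6C tumor replicate 1 (0.0616), and the endothelial call (0.0111) without Ly6G tumor replicate 1 (0.0510). The median was positive while the set test pointed down, without passing, in the glycolysis, stress response, MHC class II, matrix, oxidative stress and fibroblast lists. The higher share of passing genes was 40.0% as deposited, 5.08% on the TPM scale and 51.2% after quantile normalization. It was 6.80% on the TPM scale without S100a8 and S100a9, close to the TPM scale with them. Rescaled to pan-leukocyte genes, 10050 genes were higher and 139 lower in Ly6C tumor, and the median difference moved from 0.04 to 1.10. Of 22 lists with more lower than higher genes, 17 turned to more higher ones, and the neutrophil, eosinophil and mast cell lists still had more lower ones.

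**Figure D3:**
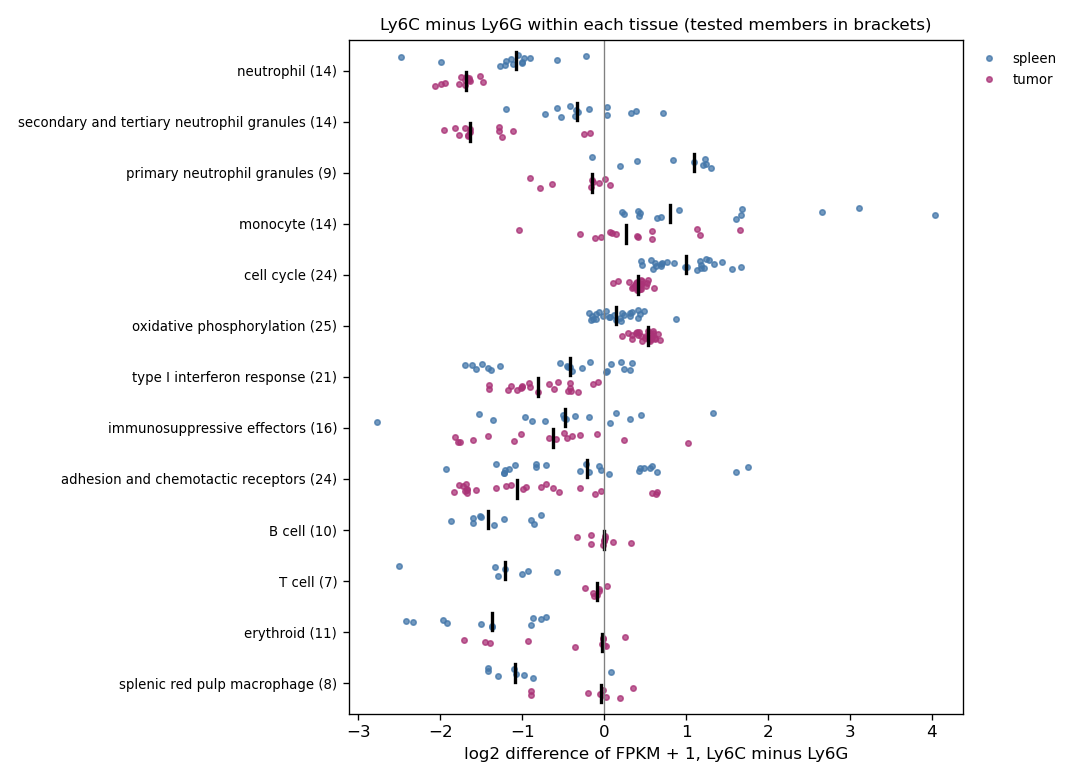
Log2 difference of FPKM + 1, Ly6C minus Ly6G (x axis), of each tested member of 13 lists (y axis) in spleen and in tumor (colors), with a bar at each list's median. Cell cycle genes had a median of 1.0 in spleen and 0.41 in tumor, and neutrophil genes -1.08 and -1.69; with pan-leukocyte rescaling, the tumor medians of the interferon and immunosuppressive lists turned positive (0.21 and 0.09).

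The last question was whether the tissue effect differed between the labels, tested as an interaction. The stem cell antigen Ly6a (3.16 ± 0.53) and the growth factor binding protein Igfbp6 (3.01 ± 0.37) rose more from spleen to tumor in Ly6C than in Ly6G, whereas Fn1 (-4.50 ± 0.83), F13a1 (-3.64 ± 0.52) and Ccl3 (-3.47 ± 0.36) had the opposite difference. Of 13610 genes, 2972 passed in limma, 820 with the higher change in Ly6C and 2152 with the lower. By list, T cell (6 of 7), B cell (6 of 10), erythroid (3 of 11) and red pulp macrophage genes (2 of 8) had the higher change in Ly6C, and cell cycle (10 of 24), primary granule (4 of 9) and secondary granule genes (3 of 14) had the lower change there. Pan-leukocyte rescaling left 0 passing genes in these last 3 lists and turned the cell cycle median to 0.50. None of Ly6g, Ly6c2, Arg1, Nos2, Cd274, Mapk3 and Mapk14 passed as deposited. Cd274 (-1.06 ± 0.39, adjusted p = 0.0707) passed without Ly6C spleen replicate 1 and without Ly6G spleen replicate 3 (lowest 0.0117), and Mapk14 (-0.65 ± 0.31, 0.161) without Ly6G spleen replicate 2 and on the TPM scale (lowest 0.0210).

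Adjusted over the list alone, 7 T cell, 6 B cell, 4 erythroid and 3 red pulp macrophage genes passed as higher in the interaction, and 12 cell cycle, 5 primary granule and 6 secondary granule genes as lower. Camera passed 9 of 31 lists, including B cell (adjusted p = 5.6e-06), and 0 held with an estimated correlation (lowest adjusted p = 0.702 with an estimated correlation, 0 lists with an unadjusted p under 0.05). The set test pointed up, without passing, against a negative median and mean in the glycolysis and eosinophil lists. It did so against a positive median and a negative mean in the hypoxia, matrix and fibroblast lists. The share with the higher change in Ly6C was 27.6% as deposited, 5.17% on the TPM scale, 54.0% with median-of-ratios factors and 51.9% after quantile normalization. It was 10.4% on the TPM scale without S100a8 and S100a9, and 97.4% after pan-leukocyte rescaling. The median difference of all genes moved between -0.49 (TPM scale) and 0.87 (pan-leukocyte). Nothing in the labels states that the 3 libraries of a group came from separate animals, so p-values measure only the spread between these samples.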

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

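The tests of other spleen cells and of scaling below were chosen only after the result was seen. For scaling, a count of passing members was tried first, and a gap between medians was tried once those counts were known. A factor per library can hardly move that gap, so the gap bears only on scaling as the whole cause.

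The difference between the labels in their tissue effect was tested directly, and 2972 genes passed. Permuting the residuals between libraries in 100 ways, the real arrangement included, gave as many genes in 1, the real one. The highest of the others was 538. A chance arrangement is argued against if the libraries are independent, which the labels do not state. Libraries of a group that share an animal or a sort would not be covered by this permutation. The genes with the highest change in Ly6C relative to Ly6G were Ly6a (a stem cell antigen of the Ly6 family; difference 3.16 ± 0.53), Igfbp6 (3.01 ± 0.37), the metallothionein Mt2 (2.38 ± 0.43), the GTPase Rhoc (2.36 ± 0.28) and the MHC class II chain H2-Aa (2.29 ± 0.66). Each rested on a lower level in Ly6C spleen than in Ly6G spleen. For example, Ly6a stood at 5.08 ± 2.46 against 25.5 ± 1.68 FPKM in spleen and at 200 ± 77.3 against 103 ± 42.5 in tumor, and Rhoc at 4.08 ± 1.37 against 19.0 ± 4.39 and at 123 ± 10.2 against 94.5 ± 6.78.

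The genes with the lowest change in Ly6C relative to Ly6G were Hgs (-5.98 ± 0.70), Fn1 (-4.50 ± 0.83), coagulation factor F10 (-3.72 ± 0.46), F13a1 (-3.64 ± 0.52) and Ccl3 (-3.47 ± 0.36). Fn1, F10 and F13a1 were higher in Ly6C spleen than in Ly6G spleen, and Ccl3 was 18.4 ± 5.69 against 5.41 ± 1.5 in spleen and 38.3 ± 9.35 against 143 ± 24.7 in tumor. Hgs is 1 of 2 identifiers of the same symbol on the same span, and the other one (ENSMUSG00000116045) had a difference of 1.63 ± 0.39, so the assignment of fragments between them limits what Hgs shows. Of these 10 genes, 9 passed under every other filter, scaling and model chosen beforehand and with each library left out. H2-Aa (adjusted p = 0.0288) did not pass without an expression filter, nor without Ly6C spleen replicate 1 or 3, Ly6C tumor replicate 1 or 3, Ly6G spleen replicate 3, or Ly6G tumor replicate 1 or 2 (range over its alternatives 0.00567 to 0.0812).

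B cell, T cell, erythroid and red pulp macrophage genes were lower in Ly6C spleen than in Ly6G spleen. Of them, 6 of 10 B cell, 6 of 7 T cell, 3 of 11 erythroid and 2 of 8 red pulp macrophage genes passed in the interaction, with the higher tumor-spleen change in Ly6C. The heavy chain Ighm was at 180 ± 39.1 against 510 ± 104 FPKM and the iron exporter Slc40a1 at 15.9 ± 3.54 against 43.4 ± 3.65. Scaling between libraries as the whole cause is argued against. The median of the 36 tested members lay below that of all genes under each scaling. In the order of scalings given next, the gaps were -1.4, -1.52, -1.52, -1.36 and -1.06 (log2). A factor per library moves nearly all genes alike and would leave no such gap. Scaling as a part of the cause stays open. The median of the 36 tested members was negative under each scaling (-1.29, -1.11, -1.55, -1.36 and -0.91), but the count that passed as lower was 35, 24, 35, 34 and 9 as deposited, on the TPM scale, with median-of-ratios factors, after quantile normalization and after pan-leukocyte rescaling. The last fit shared its spread with the tumor libraries, which can lower its count. A candidate explanation is a larger share of such cells in the Ly6G spleen libraries. The medians of these 4 lists lay within 0.34 of each other (log2). A factor per library would also give close medians, so this closeness does not separate such a share from scaling. A lower level of the same transcripts in the sorted cells was not tested. A gate on CD11b would remove B and T cells, and the labels give no gate.

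Loci that name no gene were not part of any comparison. They held signal in every library, at most 1.04% of FPKM, in Ly6G spleen replicate 1, and what they represent was not analysed here.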

How the results depend on the processing

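The tests on pan-leukocyte genes, on S100a8 and S100a9 and on the libraries of high mitochondrial share were chosen only after the result was seen.

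Direction and call were kept in 3030 of 3228 values of named genes under the other filters, scalings and models chosen beforehand and with each library left out, 174 lost their call, 24 gained one and 0 reversed. For lists, these values are those of the camera set test, of which 2644 of 2770 were kept, 33 lost, 91 gained and 2 reversed. For genes and lists alike, a turned direction counted as reversed only where a fit made a call. The majority direction of the passing members of a list, which is another measure, turned with the scaling in several lists. In Ly6C between tissues, 43 of 43 named genes kept their call in all these fits, in Ly6G 45 of 47, in spleen 26 of 44, in tumor 15 of 33 and in the interaction 15 of 18. Calls of named genes and set tests were not computed under the settings added after the data were seen. Of those settings, pan-leukocyte rescaling moved the median change of all genes in Ly6C between tissues from 0.27 to 2.99. The reversed lists were glycolysis in the interaction (median -0.26 after quantile normalization, adjusted p = 0.0415) and fibroblast genes between the labels in tumor (0.30 without Ly6G tumor replicate 3, 0.0351, but -0.28 without Ly6G tumor replicate 2, 0.106), and the cause was not tested.

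A filter at 5 FPKM gave 6694 genes in Ly6C and 6648 in Ly6G between tissues, because fewer genes were tested. The TPM scale gave 4931 genes in the interaction. A fit of the spleen groups alone gave 2586 against 4171, while one of the tumor groups alone gave 2734 against 1974. Each had fewer samples behind the spread, which alone does not account for opposite changes. Array weights gave 3433 in tumor. Pan-leukocyte rescaling gave 262 in spleen, 10189 in tumor and 1846 in the interaction. Its spleen count can fall through the spread shared with the tumor libraries. Without both libraries of high mitochondrial share there were 260 in tumor and 1417 in the interaction, again with fewer samples. The correlation of the tissue effects moved to 0.931 and 0.910 with a pseudocount of 0.1 and 5, 0.911 with no filter, 0.926 with a filter at 5 FPKM, 0.922 on the TPM scale, 0.931 after pan-leukocyte rescaling, 0.923 without S100a8 and S100a9 and 0.921 without the libraries of high mitochondrial share, all more than 0.0032, the SD over leaving out single libraries. Apart from the cases given, the cause was not tested.

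Leaving out a library gave 9930 to 10419 genes in Ly6C and 9742 to 10165 in Ly6G between tissues, 3317 to 4150 in spleen, 746 (without Ly6G tumor replicate 3) to 1324 (without Ly6G tumor replicate 1) in tumor, 2095 to 3124 in the interaction, and a correlation of 0.910 to 0.919. With the replicate number as a block, 10402, 10366, 3941, 1619 and 2729 genes passed in the 5 comparisons. Whether the numbers pair the samples is not known. The residuals of samples of the same number in 2 groups had r of -0.36 to 0.28, and those of different numbers reached 0.427, in spleen. With 3 libraries per group, such correlations cannot settle whether samples share an animal, so a pairing under other numbers stays open.

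With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. Fits of 2 groups gave 10216, 10336, 2586 and 2734 genes in Ly6C between tissues, Ly6G between tissues, spleen and tumor, and the highest of the other splits gave 0, 0, 1 and 3. In each, 1 of the 10 splits, the real one, gave as many.

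Depth limits genes near 0.0237 to 0.0301 FPKM, which would be a single fragment on 2 kb. The changes of Krt8 and of other genes near 0 in spleen depend on the pseudocount, and their sizes are not bounds.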

Other observations

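The tests of cells of another type, of a lower share of the same neutrophils, of swapped labels and of dividing granulocytes were chosen only after the result was seen, and the last of these was restricted to 4 scalings after the values under pan-leukocyte rescaling (8 of 24 cell cycle and 2 of 9 primary granule genes higher) were known.

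Cytoskeletal, adhesion and basement membrane genes made up a further set of tumor transcripts. Of 26 genes of an adherent cell list, 20 were tested, and 18 were higher in tumor in each label (medians 2.52 in Ly6C and 2.65 in Ly6G). The laminin chain Lamc1 stood at 39.3 ± 1.98 FPKM in Ly6C tumor against 1.49 ± 0.983 in Ly6C spleen, and at 39.5 ± 2.79 against 0.445 ± 0.203 in the Ly6G libraries. The actin regulators Cald1 and Cttn reached 45.1 ± 6.70 and 29.9 ± 1.10 in Ly6C tumor, while Pdlim7 did not differ. Of the 26, 10 had a mean of at least 1 FPKM in a spleen group, and 0 were in another list.

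Of 20 genes shared by most leukocytes, 19 were lower in tumor in each label (medians -3.54 and -2.53), and 16 were lower in Ly6C tumor than in Ly6G tumor (median -1.12). The adaptor Tyrobp fell from 914 ± 59.4 to 134 ± 49.6 FPKM in Ly6C and from 1395 ± 29.6 to 322 ± 83.3 in Ly6G. The phosphatase Ptpn6 fell from 192 ± 4.39 to 16.8 ± 4.89 and from 175 ± 5.49 to 32.7 ± 8.69. One of the 20, the integrin chain Itgb2, is also in another list. The cytokine Il1b stood at 274 ± 62.9 in Ly6C tumor and 933 ± 278 in Ly6G tumor.

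The tumor libraries held keratin and adherent cell transcripts and few leukocyte transcripts. A lower share of leukocytes as the whole cause of the fall of granule genes is argued against, because after pan-leukocyte rescaling the 23 granule genes still had medians of -2.60 in Ly6C and -2.24 in Ly6G, with 18 and 19 of them lower and 2 higher in each. The share of S100a8 and S100a9 in spleen, at most 30.5% of a library's FPKM, is argued against by its size. Without both genes the adherent cell median was 3.33 in Ly6C and 3.68 in Ly6G. With them it was 3.47 and 3.77 on the same TPM scale. Removing a share of that size can shift a median only slightly, so this outcome was known in advance and is no independent test. Cells of another type in the tumor libraries, such as tumor cells, are a candidate source of the keratin and adherent cell transcripts. Of the 26 adherent cell genes, 18 were higher in both labels, but that list was written after the first fit. The count therefore describes the pattern and is no independent test of this source. A change of the sorted cells themselves between the tissues stays open and was not tested, and the labels give no gate or purity.

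Spleen libraries labelled Ly6C held neutrophil granule transcripts near the level of those labelled Ly6G. The same neutrophils at a uniformly lower share are argued against, since the mean difference of 21 granule genes (0.29) lay 1.48 above that of 12 neutrophil markers (-1.20), with a permutation p of 1e-05 over genes, the smallest that 100000 permutations can give, and genes are not independent. Swapped labels are argued against, because the lowest Ly6g value of the Ly6G spleen libraries was 2.82 times the highest of the Ly6C ones. More dividing immature granulocytes in the Ly6C libraries may be involved, as at least 20 of 24 cell cycle genes were higher under the deposited values and the other 3 scalings, but only 4 or 5 of 9 primary granule genes were, so this cannot be told apart from dividing monocyte precursors.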
